A study of Mus musculus with 2 samples.

How the data were processed

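Chromatin immunoprecipitation with sequencing (ChIP-seq) was done with an antibody against H3K27me3 on forebrain of mouse embryos at embryonic day 14.5, per the labels. The 2 samples form 1 group and are biological replicates from separate pools of embryos of both sexes. Replicate 1 came from 24 embryos and has 2 technical replicates, and replicate 2 came from 34 embryos and has 1. The size range in the labels is 300 to 500, taken here as base pairs. The labels name a possible control experiment, which was not analysed here.

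The deposited data were 4 peak lists in narrowPeak format on the mm10 build, per the text notes deposited with the files. Replicate 1 and replicate 2 each have a list, named in those notes as derived from that replicate's alignment and from further files whose kind the notes do not name. A pooled list was derived from both alignments. A replicated list was derived from both replicates' lists and the pooled list, and the rule that selects its peaks is not given in the sources used here. The aligner, the peak caller and the thresholds are also not given in the sources used here. The lists hold no read counts, so the sequencing depth of each sample is unknown and no interval that needs a depth was computed.

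Each list holds the authors' deposited integer score per peak, which was read and not used in any comparison. The authors' deposited signal value per peak is an enrichment whose reference is not stated, and it was used only to describe, rank or filter peaks within a list. The authors' deposited −log10 p-value (replicate lists) and −log10 q-value (all lists) were used to order or filter peaks. Another deposited column, the offset of the summit from the peak start per the format, was read and not used. No peak lay beyond the end of a chromosome of the GRCm38.p6 reference, the assembly that mm10 also names. Chromosome lengths, sequence and the GENCODE M21 annotation of that build were used for all coordinates, which are given 1-based. RefSeq annotation of the same assembly was used only to annotate the 12 replicated peaks with the highest −log10 q.

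The annotation holds 21938 protein-coding genes on chromosomes 1 to 19, X and Y, and 21911 with a unique symbol were kept. A promoter was the 1 kb either side of the 5′ end of the gene record, and a gene was occupied if a peak overlapped that window by at least 1 bp. The main results use the replicated list, and the shares of the gene lists have values from each replicate's own list beside them. The share of each replicate's peaks that overlapped the other's by at least 1 bp, the number of occupied promoters and the share of covered bases per class of annotation were each set against 1000 circular shifts of the peaks within chromosomes, beginning 3 Mb from the start of each. Classes were assigned in the order promoter, exon, intron, intergenic. These randomizations are two-sided permutation tests, and 0.001 is the smallest p they can give. Peaks of replicate 2 were also paired with the peak of replicate 1 that overlapped them most, and Spearman's rho of the enrichment was computed across pairs without a p-value.

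For gene lists, the share of members with an occupied promoter was compared with all other protein-coding genes by a two-sided Fisher's exact test, and p-values were adjusted over the 19 lists by the Benjamini-Hochberg method. Of the 623 symbols written in the lists, 621 matched the annotation; H19 and Amy2b did not. The lists hold 608 genes, of which 13 are in more than 1 list: Cdkn1c, Cdx1, Cspg4, Fgf4, Foxc1, Igf2, Isl1, Nkx2-2, Otx2, Pdgfra, Sox10, Tbx3 and Ttr. Tests of 5 pairs of lists used the same exact test with adjustment over the pairs. The spread of peaks was the number of base pairs covered within 5 kb either side of the 5′ end of an occupied gene, a window of 10001 bp. The median of each list with 5 or more occupied members was compared with that of the other occupied genes by a two-sided permutation test with 100000 resamples. The smallest p of these resamples is 1e-05. Families of gene symbols were formed from the letters before the first digit or hyphen, and the 283 families with 10 or more members were tested like the lists. The ratio of observed to expected CpG dinucleotides was computed in the promoter window, promoters were divided into 10 equal groups by it, and the mean ratio of occupied and other promoters was compared by permutation with 100000 resamples. Replicated peaks 3 kb or less apart were merged into domains. The threshold for an adjusted p was 0.05. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Genes and peaks are not biological replicates, and neighbouring genes can share a domain, so these p-values describe these lists of peaks and not the spread between animals.

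The tests, the gene lists and most alternatives were fixed before the data were examined. The genes named were set by a rule. For each list, the rule takes up to 3 occupied members with the highest enrichment at the promoter and the first 2 unoccupied members in the order written. Over all genes, it takes the 10 with the highest promoter enrichment and the genes of the 15 widest domains. It also takes, for each replicate, the 5 with the highest enrichment that had no peak in the other replicate or in the replicated list. For families, it takes the 2 members of highest enrichment in the 5 families of lowest adjusted p in each direction. Ezh2, Eed, Suz12, Foxg1, Hoxd13, Actb and Cdkn2a are always named. Other members of lists and families are named where the text says which were occupied, and these were chosen after their values were seen.

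The alternatives were promoter windows of 0.5 and 2.5 kb, any annotated protein-coding transcript start, the pooled list, each replicate's own list (which leaves out the other replicate), a −log10 q of 5 or more, a background matched on CpG ratio, and 1 gene per 100 kb. For overlap, they were a 50% reciprocal overlap, equal list lengths, merged peaks and shifts of at most 1 Mb. For spread, a window of 10 kb either side was tried, and for domains, merging at 1 and 10 kb. After the data were seen, 3 more were added: replicated peaks that overlap both replicates' lists, a −log10 q of 2 or more, and chromosome Y left out.

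Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data first. On simulated occupancy of the 21911 genes, the list test called 97.2% of raised lists and 0.923% of unraised lists, and the family test called 79.4% of raised families and 0.228% of others. Occupancy was also simulated to rise steadily with CpG ratio alone, with lists drawn from CpG-rich promoters. There, Fisher's exact test called 14.5% of lists and the CpG-matched test called 0%. In the real peaks the occupied share did not rise steadily with CpG ratio, so these rates need not hold for them. The shift test called 2.5% of independent pairs of lists and 100% of pairs with planted shared peaks. The spread test called 0.75% of unraised and 100% of raised lists. The comparison of CpG means called 7.5% of 40 simulations without an effect and 100% of those with one.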

Results

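H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complex 2 places on silenced genes, was mapped by ChIP-seq in mouse forebrain at embryonic day 14.5. At this stage the forebrain holds dividing progenitors and newly formed neurons. The 2 biological replicates came from pools of 24 embryos (replicate 1) and 34 embryos (replicate 2), each of both sexes, and they form the only group. The labels give no second tissue, age or treatment, so the comparisons are between the replicates and between genes and regions within this tissue. The measurements are the authors' peaks, with an enrichment value per peak whose reference is not stated. Read depth per sample is unknown.

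Both replicates had peaks at the promoters of all 39 Hox genes, which set position along the body axis behind the forebrain, and of all 44 listed regulators of midbrain, hindbrain and spinal cord. Neither replicate had a peak at any of 36 housekeeping promoters, among them Actb (cytoplasmic actin) and Gapdh (a glycolytic enzyme), and the pooled list had a peak at 1 of the 36. Of the 2398 protein-coding promoters occupied in replicate 2, 92.2% were also occupied in replicate 1, and 2210 were occupied in both. A further 1613 promoters were occupied in replicate 1 only and 188 in replicate 2 only. The promoters with the highest enrichment in replicate 1 and no peak in replicate 2 or the replicated list belonged to Aatf (5.93), Dgkk (5.35), the unconventional myosin gene Myo1d (5.08), Zfp580 (4.82) and the protocadherin gene Pcdhgb6 (4.82). Those with the highest enrichment in replicate 2 and no peak in replicate 1 or the replicated list belonged to Lxn (4.66), Kctd8 (4.51), Smim10l1 (4.51), C1qtnf4 (4.35) and 2310034G01Rik (4.35). In the pooled list, Lxn, Smim10l1, C1qtnf4, 2310034G01Rik, Dgkk, Myo1d and Zfp580 also had a promoter peak. Replicated peaks lay nearby at some of these genes, covering 3669 bp within 5 kb at Zfp580, 3580 bp at Aatf and 2038 bp at C1qtnf4.

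Replicate 1 had 64556 peaks covering 26.1 Mb, with a median width of 255 bp, and replicate 2 had 27286 peaks covering 11.2 Mb, with a median width of 280.0 bp. Most of these peaks were weak by the authors' q-value. A −log10 q of 2 or more was reached by 39.9% in replicate 1 and 40.3% in replicate 2, and 5 or more by 10.5% and 9.25%. The lowest −log10 p was 2.00 and 2.05. In replicate 1, 24.0% of peaks (95% interval 23.7 to 24.3) overlapped a peak of replicate 2, against 0.828% ± 0.0991 (SD of 1000 shifts) for shifted peaks (permutation by circular shifts, two-sided, p = 0.001). In replicate 2, 71.8% (71.3 to 72.3) overlapped a peak of replicate 1, against 2.05% ± 0.257 for shifted peaks (the same permutation test, p = 0.001, the smallest it can give). Within each list, overlap was highest among the peaks of highest enrichment. In replicate 1 it was 9.35% in the lowest of 5 equal groups by enrichment and 64.5% in the highest, and in replicate 2 it was 58.7% and 95.7%. Across 19593 overlapping pairs of peaks, Spearman's rho of the enrichment was 0.359, a description across peaks that are not independent. The shares depended on the definition: with a 50% reciprocal overlap they were 9.79% of replicate 1 and 23.2% of replicate 2, and with equal list lengths 43.5% and 60.8%. The chance values depended on the shifts: with shifts of at most 1 Mb, which keep peaks in the same region, they were 2.1% ± 0.414 (replicate 1) and 5.37% ± 1.16 (replicate 2), so the ratio to chance was 11.4 and 13.4, against 29.0 and 35.1 with the main shifts.

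The replicated list, used for the results on genes, had 17421 peaks covering 16.5 Mb (0.604% of the genome), with a median width of 576 bp and a widest peak of 42417 bp over Hoxb3 and Hoxb4. All 17421 were also in the pooled list of 50747 peaks. A peak of replicate 1 overlapped 96.6% of them (96.3 to 96.9), a peak of replicate 2 overlapped 74.9% (74.3 to 75.6), and 72.2% overlapped both. Only 110 overlapped neither. For the gene lists, shares from each replicate's list are given beside those of the replicated list, which has no replicate error of its own. Enrichments of genes and spread of peaks are those of the replicated list unless a replicate is named. The enrichment of a gene or promoter is the highest value of any peak that overlaps the promoter by at least 1 bp. It describes the whole peak, which may lie mostly outside the promoter. Enrichments can differ between lists: in replicate 2, Nkx2-5 had 4.05 against 8.10, and Cdx1 5.11 against 9.11.

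The 10 promoters of highest enrichment all belonged to genes of transcription factors. The maternally expressed imprinted gene Klf14, which encodes a zinc finger factor, was first (14.2; peak on chromosome 6 from 30955461 to 30959673, mm10), followed by Hoxa7 (12.4), the mesodermal regulator Twist2 (11.6), Hoxa11 (10.9), the neuronal factor Bhlhe23 (10.9), Hoxc6 (10.7) and Foxf1 (10.1), a regulator of lung and gut mesenchyme. Hoxb3, Hoxb4 and the activity-regulated factor Egr3 each had 9.91. Hoxb3 and Hoxb4 lie under the same replicated peak of 42417 bp, so theirs is 1 value counted at 2 promoters. The order differed in the list of replicate 2. Twist2 (11.1) exceeded Klf14 (10.5) there, and Hoxa11, Hoxb3 and Hoxb4 had 5.40, 6.19 and 6.20. No replicated peak lay at the promoters of Ezh2, Eed and Suz12, the core subunits of Polycomb repressive complex 2. In all, 2480 of 21911 protein-coding promoters were occupied (11.3%, 95% interval 10.9 to 11.7), against 325 ± 25.4 (SD of 1000 shifts) for shifted peaks, a ratio of 7.63 (permutation by circular shifts, two-sided, p = 0.001). The count was 3823 with the list of replicate 1, 2398 with that of replicate 2, and 1467 with peaks of −log10 q of 5 or more.

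Hox genes, listed regulators of other parts of the embryo and secreted morphogens were occupied more often than other genes. The lists do not fully separate other regions from forebrain. Isl1, for example, is in both the midbrain, hindbrain and spinal cord list and the forebrain neuron subtype list. Whether further members of the lists for other regions also act in forebrain was not examined. All 39 Hox genes were occupied (95% interval from 91.0%), against 11.2% of other genes (Fisher's exact test, two-sided, here and for all lists, adjusted p = 6.1e-37). Hox genes share domains and are not independent units, which this interval and p-value do not allow for. Over the 12 alternatives, the highest adjusted p for this list was 0.000126 (Fisher's exact test or permutation). All 44 midbrain, hindbrain and spinal cord regulators were occupied (from 92.0%; Fisher's exact test, adjusted p = 3.1e-41), and Gata3, Ptf1a and Gata2 had the highest enrichment among them (8.60, 8.43 and 7.77). Of 67 regulators of mesoderm, endoderm and neural crest, 55 were occupied (82.1%, 70.8 to 90.4; Fisher's exact test, adjusted p = 7.6e-40), led by Twist2, Foxf1 and Msx2 (9.42), a factor of limb and skull development. The 12 unoccupied members included the myogenic factors Myf5 and Myf6. Of 54 secreted morphogens and their antagonists, 43 were occupied (79.6%, 66.5 to 89.4; Fisher's exact test, adjusted p = 1.9e-30), with Wnt3a (8.93), Wnt1 (8.43) and Fgf3 (8.43) highest. Wnt5b and Wnt7a had no replicated peak but had a peak in replicate 1. The share was 100% in both replicates for the first 2 lists, 83.6% and 82.1% for the mesoderm list, and 90.7% and 74.1% for the morphogens.

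Genes that pattern the forebrain itself were divided. Of 40 forebrain patterning and progenitor regulators, 26 were occupied (65.0%, 48.3 to 79.4; 77.5% in replicate 1 and 60.0% in replicate 2; Fisher's exact test, adjusted p = 4.0e-15). The highest enrichment was at Six3 (8.76) and Rax (7.82), which act in the anterior forebrain and eye field, and at Gsx1 (8.32), a factor of the ventral telencephalon. Dlx1, Dlx2, Dlx5, Dlx6 and Nkx2-1, which act in the ventral telencephalon, were occupied, as were Pax6, Emx1, Neurog1 and Neurog2, which act in dorsal progenitors. Whole forebrain was used and expression was not measured. Peaks at these or other genes therefore do not show which cells carry the mark or whether the gene is silent. The unoccupied members were Foxg1, Emx2, Otx1, Hes1, Hes5, Sox1, Sox2, Sox3, Ascl1, Arx, Nr2f1, Nr2e1, Tcf7l2 and Gli3. At Foxg1, which specifies the telencephalon, no list had a promoter peak, and replicated peaks covered 620.0 of the 10001 bp around the 5′ end. At Emx2, a factor of the dorsal telencephalon, no list had one either, and 2636 bp were covered. Of 31 regulators of forebrain neuron subtypes, 12 were occupied (38.7%, 21.9 to 57.8; 51.6% and 35.5% in replicates 1 and 2; Fisher's exact test, adjusted p = 0.000182). Neurod2 (6.46), Satb2 (6.29) and Eomes (5.63) had the highest enrichment, and Tbr1 was also occupied. In the lists of replicates 1 and 2, Neurod2 was the lowest of these 3 (3.86 and 3.25). Satb2 had 6.69 and 4.81 there, and Eomes 4.77 and 4.59. Neurod6 and Bcl11a, both expressed in cortical neurons, had no peak in any list.

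Synaptic and mature neuron genes were occupied more often than genes that all neurons use, a difference that did not pass with peaks of −log10 q of 5 or more (38.2% and 13.3%; Fisher's exact test, adjusted p = 0.0567). Of 34 synaptic and mature neuron genes, 21 were occupied (61.8%, 43.6 to 77.8; 76.5% and 64.7% in replicates 1 and 2; Fisher's exact test, adjusted p = 8.4e-12). Chat, the enzyme that makes acetylcholine, had the highest enrichment (7.49), followed by the vesicular glutamate transporter gene Slc17a7 (6.62) and the neuropeptide gene Cck (6.13). This order did not hold in the lists of replicates 1 and 2. There Slc17a7 (6.42 and 6.61) exceeded Chat (5.62 and 4.35), and Cck had 6.69 and 4.22. The AMPA receptor genes Gria1 and Gria2 had no peak in any list. Of 30 pan-neuronal genes, 7 were occupied (23.3%, 9.93 to 42.3; 33.3% and 23.3%), a share that did not pass the threshold (Fisher's exact test, adjusted p = 0.107). They were Crmp1 (4.97), Ank3 (4.97), Rbfox1 (4.64), Cntn2, Ina, Nefl and Rtn1. Tubb3, the neuronal beta-tubulin gene, and Dcx, which encodes a microtubule protein of migrating neurons, had no peak in any list. The pan-neuronal share passed with the list of replicate 1, the pooled list, a 2.5 kb window and any transcript start (adjusted p = 0.0375, 0.0172, 0.0202 and 0.00443, Fisher's exact test).

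The plot of occupancy by gene list shows the shares for all 19 lists.

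**Figure D1:**
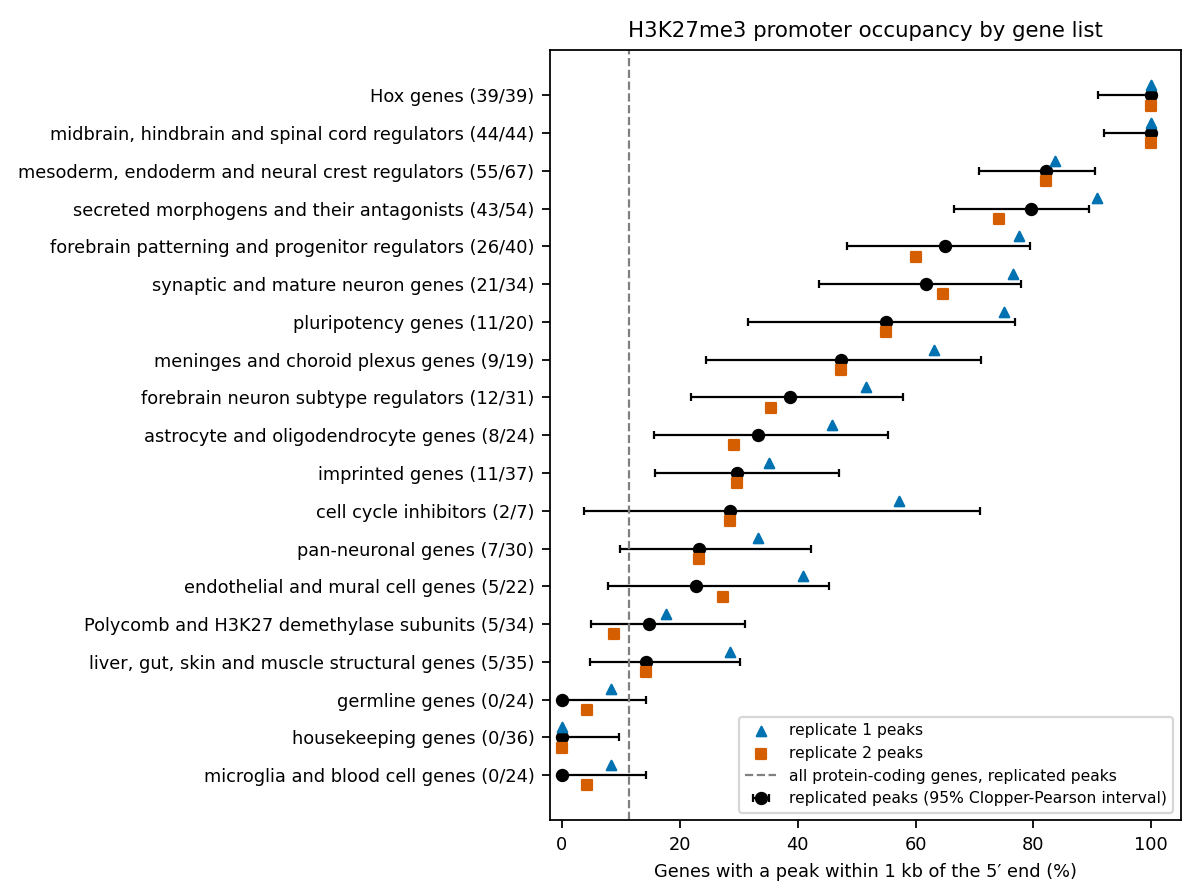
Share of the members of each gene list with a peak within 1 kb of the 5′ end, in percent. Circles show replicated peaks with exact 95% intervals, triangles replicate 1, squares replicate 2, and the dashed line the 11.3% of all protein-coding genes; the shares run from 0% of housekeeping, germline, and microglia and blood cell genes to 100% of Hox genes and of midbrain, hindbrain and spinal cord regulators.

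Among genes of other cell types in or around the brain, 9 of 19 meninges and choroid plexus genes were occupied (47.4%, 24.4 to 71.1; 63.2% and 47.4% in replicates 1 and 2; Fisher's exact test, adjusted p = 0.000202). Foxc1 (6.46), a factor of the meninges, Aldh1a2 (6.29), which makes retinoic acid, and Igf2 (5.65) were highest, and the collagen gene Col3a1 and the proteoglycan gene Dcn were unoccupied. Of 24 astrocyte and oligodendrocyte genes, 8 were occupied (33.3%, 15.6 to 55.3; 45.8% and 29.2%; Fisher's exact test, adjusted p = 0.00637). These were the oligodendrocyte lineage factors Olig1 (9.42), Nkx2-2 (7.61), Sox10 (7.28), Olig2, Myrf and Sox8, the receptor gene Pdgfra and the gap junction gene Gja1, and the 16 unoccupied members were genes of both cell types, of which Gfap and Aqp4 had no peak in any list. Of 22 endothelial and mural cell genes, 5 were occupied (22.7%, 7.82 to 45.4; 40.9% and 27.3%; Fisher's exact test, adjusted p = 0.122), led by Cldn5 (7.11), Flt1 (5.96) and Esam (5.55). Pecam1 and Cdh5 were unoccupied. None of 24 microglia and blood cell genes was occupied (0%, up to 14.2%; 8.33% and 4.17%; Fisher's exact test, adjusted p = 0.122), and Aif1 and Cx3cr1 had no peak in any list. The endothelial share passed the threshold with each replicate's own list and with the pooled list (adjusted p = 0.0122 for replicate 1, 0.0421 for replicate 2 and 0.00284 for pooled, Fisher's exact test).

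Of 20 pluripotency genes, which are active in the early embryo, 11 were occupied (55%, 31.5 to 76.9; 75% and 55% in replicates 1 and 2; Fisher's exact test, adjusted p = 6.6e-06). Klf2 (6.29), Tbx3 (6.22) and Utf1 (6.13) were highest, Pou5f1 was occupied, and Nanog and Zfp42 were not, although Nanog had a peak in replicate 1. Of 37 imprinted genes, 11 were occupied (29.7%, 15.9 to 47.0; 35.1% and 29.7%; Fisher's exact test, adjusted p = 0.00377). They included Dio3 (9.42), which inactivates thyroid hormone, Rasgrf1 (7.77) and the potassium channel gene Kcnq1 (7.61), while Igf2r and Cdkn1c had no replicated peak at the promoter. Cdkn1c had one in replicate 1 (3.21). None of 24 germline genes was occupied (0%, up to 14.2%; 8.33% and 4.17%; Fisher's exact test, adjusted p = 0.122), Ddx4 and Dazl among them. Of 35 structural genes of liver, gut, skin and muscle, 5 were occupied (14.3%, 4.81 to 30.3; 28.6% and 14.3%; Fisher's exact test, adjusted p = 0.589). Cdx1 (9.11), a homeobox factor gene that is also among the mesoderm and endoderm regulators, the muscle creatine kinase gene Ckm (8.60), Nphs1 (7.77), Acta1 and Lor were the 5, and the liver genes Alb and Afp had no peak in any list. The share passed against promoters of like CpG ratio (adjusted p = 0.0409 by permutation), and the difference changed sign with any transcript start (-1.22 percentage points) and with 1 gene per 100 kb (-13.2), where it did not pass.

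Of 34 genes for Polycomb and H3K27 demethylase subunits, 5 were occupied (14.7%, 4.95 to 31.1; 17.6% and 8.82% in replicates 1 and 2; Fisher's exact test, adjusted p = 0.589). These were Cbx8 (7.49), Cbx4 (6.95), Epop (4.63), Pcgf5 and Phf19, and Ezh1 was unoccupied. With a promoter window of 2.5 kb, 11 of the 34 were occupied (32.4%) and the share passed the threshold (adjusted p = 0.00678, Fisher's exact test). The difference from other genes changed sign with the list of replicate 2 (-2.12 percentage points) and with 1 gene per 100 kb (-4.12), where it did not pass. Of 7 cell cycle inhibitors, 2 were occupied (28.6%, 3.67 to 71.0; 57.1% and 28.6%; Fisher's exact test, adjusted p = 0.205): Cdkn2a (6.66), which encodes p16 and p19, and its neighbour Cdkn2b (3.57), which had no peak of −log10 q of 5 or more. The share of cell cycle inhibitors passed with the list of replicate 1, with a 2.5 kb window and with any transcript start (adjusted p = 0.0281, 0.0015 and 0.00103, Fisher's exact test). Cdkn1b had no promoter peak in any list. Cdkn1a had no replicated peak at the promoter but had one in replicate 1 (2.64) and in the pooled list (2.03). None of the 36 housekeeping genes was occupied (0%, up to 9.74%; 0% in both replicates), a lower share than among other genes (Fisher's exact test, adjusted p = 0.0471). That call was lost with a promoter window of 0.5 kb, with peaks of −log10 q of 5 or more, with replicated peaks overlapping both replicates, and with 1 gene per 100 kb (adjusted p = 0.0708, 0.234, 0.0718 and 0.651 by Fisher's exact test). Of the 19 lists, 11 were occupied more often than other genes, 1 less often and 7 did not pass the threshold.

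Lists were also compared with each other in 5 pairs. The regulators of midbrain, hindbrain and spinal cord were occupied more often than those of forebrain patterning (100% and 65.0%; Fisher's exact test, adjusted p = 3.7e-05). The regulators of mesoderm, endoderm and neural crest were not shown to differ from those of forebrain patterning (82.1% and 65.0%; Fisher's exact test, adjusted p = 0.0624). Forebrain patterning regulators were occupied more often than neuron subtype regulators (65.0% and 38.7%; Fisher's exact test, adjusted p = 0.0417). Pan-neuronal genes were occupied less often than synaptic and mature neuron genes (23.3% and 61.8%; Fisher's exact test, adjusted p = 0.00436) and more often than housekeeping genes (23.3% and 0%; Fisher's exact test, adjusted p = 0.00436). With peaks of −log10 q of 5 or more, the last 3 differences no longer passed (adjusted p = 0.22, 0.0567 and 0.0567, Fisher's exact test). The mesoderm list did differ from forebrain patterning in 5 of 9 alternatives: with those peaks, with the list of replicate 2 alone, with peaks of −log10 q of 2 or more, with replicated peaks overlapping both replicates and with any transcript start (adjusted p = 0.00148, 0.0273, 0.0273, 0.0374 and 0.046, Fisher's exact test). Forebrain patterning was also not shown to differ from neuron subtype regulators with the list of replicate 2 alone and with peaks of −log10 q of 2 or more (adjusted p = 0.0561 and 0.0962, Fisher's exact test).

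Around occupied promoters, peaks spread farther at Hox genes and at the listed regulators of other regions than at other occupied genes. Within 5 kb either side of the 5′ end, replicated peaks covered a median of 9772 bp at Hox genes, 8941 bp at midbrain, hindbrain and spinal cord regulators and 8126 bp at mesoderm, endoderm and neural crest regulators, against 2503 bp over all 2480 occupied genes (quartiles 1156 and 4451). Each of these 3 lists was wider than the other occupied genes (permutation test, two-sided, adjusted p = 5e-05). Neighbouring Hox genes share domains, which the permutation did not allow for. Neuron subtype regulators had 6603.5 bp (adjusted p = 0.00095), forebrain patterning regulators 6403 bp (adjusted p = 7.5e-05) and morphogens 5042 bp (adjusted p = 0.00012, all by permutation). Astrocyte and oligodendrocyte genes had 5507 bp (adjusted p = 0.0244), meninges and choroid plexus genes 5388 bp (adjusted p = 0.0236) and imprinted genes 4768 bp (adjusted p = 0.0367, all by permutation). Synaptic and mature neuron genes had 3176 bp (adjusted p = 0.362) and pan-neuronal genes 3040.0 bp (adjusted p = 0.62), neither past the threshold by permutation. Endothelial and mural cell genes (4552 bp), Polycomb subunits (4455 bp), structural genes (3515 bp) and pluripotency genes (1911 bp) did not pass it either, with adjusted p by permutation of 0.148, 0.15, 0.496 and 0.536. With the list of replicate 1 alone, the astrocyte and oligodendrocyte list no longer passed (adjusted p = 0.493) and the synaptic list did (adjusted p = 0.011, permutation tests).

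The widest domains, formed by joining replicated peaks 3 kb or less apart, lay over the 4 Hox clusters. The HoxA domain spanned 182.5 kb on chromosome 6 (52146151 to 52328660) from Hoxa1 to Evx1, and replicated peaks covered 88.2% of it. The HoxC domain spanned 178.0 kb on chromosome 15 (102898597 to 103076555), the HoxB domain 135.8 kb on chromosome 11 (96246671 to 96382435) and the HoxD domain 126.4 kb on chromosome 2 (74642663 to 74769046), and peaks covered 92.6%, 93.2% and 91.4% of them. The list of replicate 1 covered 87.6% of the HoxA domain and that of replicate 2 covered 74.0%. Hoxd13, which patterns the distal limb, lay in the HoxD domain with a promoter enrichment of 6.29. Beyond these 4, the widest domains held Nkx2-1, the ventral forebrain and thyroid factor (105.6 kb on chromosome 12, 56440174 to 56545811), and Pax3, a factor of dorsal neural tube and neural crest (86.3 kb on chromosome 1, 78135138 to 78221398). They were followed by domains over Zic1 and Zic4 (59.6 kb), Dmbx1 and Faah (55.1 kb), Nr2f2 (54.8 kb), an intragenic part of Kcnq1 (53.2 kb), Ttll6 and Hoxb13, a HoxB gene outside the HoxB domain (51.3 kb), Tfap2a (49.5 kb), Cdkn2a and Cdkn2b (48.4 kb), Fgfr2 (48.3 kb) and Hand2 (48.3 kb). There were 6302 domains with a median width of 1516 bp, and the 502 of at least 10 kb held 46.1% of all covered base pairs. The number of domains was 28542 with the list of replicate 1 and 9490 with that of replicate 2.

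**Figure D2:**
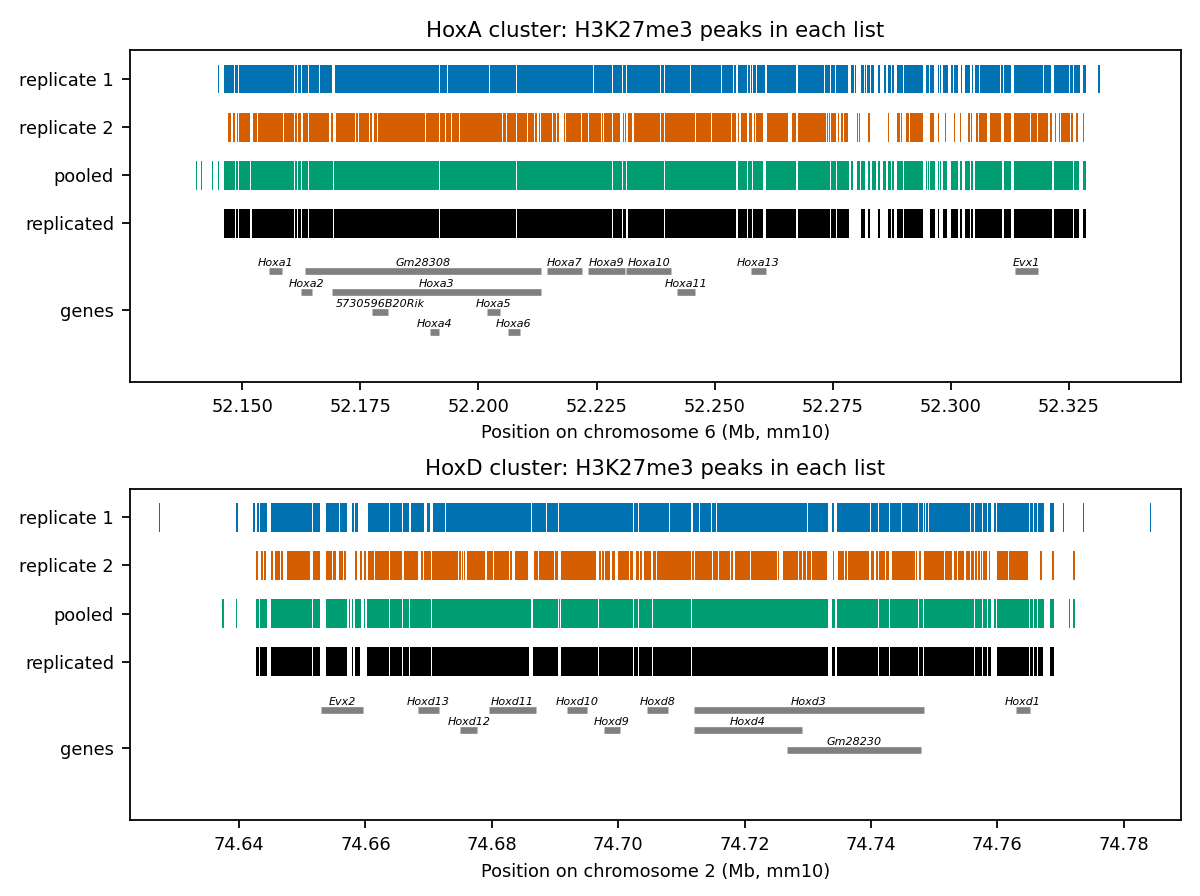
Peaks of each list over the HoxA and HoxD clusters, with position in Mb (mm10) on the horizontal axis, 1 row of bars per peak list and protein-coding genes as grey bars. Replicated peaks cover 88.2% of the HoxA domain and 91.4% of the HoxD domain.

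Families of gene symbols were searched in the same way. The Wnt family of secreted ligands had 17 of 19 promoters occupied (89.5%), the Nkx homeobox family 13 of 14 (92.9%), Hoxa 11 of 11, Hoxb 10 of 10 and the Tbx family of T-box factors 9 of 13 (69.2%). These had the lowest adjusted p among the families occupied more often (7.6e-13, 3.5e-10, 1.8e-09, 1.4e-08 and 4.4e-05 by Fisher's exact test). Nkx1-1 (8.76), Nkx2-5 (8.10), Tbx15 (7.77) and Tbx21 (7.44) led the Nkx and Tbx families. Odorant receptor genes (Olfr) were occupied at 0 of 1134 promoters (0%, up to 0.325%) and vomeronasal receptor genes (Vmn) at 0 of 330 (0%, up to 1.11%). Predicted genes (Gm) were occupied at 36 of 1506 (2.39%), with Gm28308 in the HoxA cluster (9.83) and Gm49601 (9.26) highest. Zinc finger genes (Zfp) were occupied at 11 of 394 (2.79%), with Zfp296 (6.95) and Zfp853 (5.96) highest, and histone genes (Hist) at 0 of 67. These were the 5 families with the lowest adjusted p among those occupied less often (Fisher's exact test, adjusted p = 8.9e-59 for Olfr, 6.5e-16 for Vmn, 2.9e-38 for Gm, 2.0e-08 for Zfp and 0.0105 for Hist). Of 283 families, 19 were occupied more often and 6 less often than other genes. Against promoters of like CpG ratio, 16 of the 19 and 5 of the 6 were also called, and the Vmn family was not (adjusted p = 0.337 by permutation). The share expected from CpG ratio was 1.15% for Olfr, 1.03% for Vmn and 5.91% for Gm. For Olfr and Gm the difference was thus -1.15 and -3.52 percentage points, against -11.9 and -9.59 from all other genes. For Zfp and Hist the expected share was 14.6% and 13.8%, so their shortfall did not shrink. With 1 gene per 100 kb, 10 families were higher, of which 9 were among the 19, and 4 of the 6 were still lower. The Hoxa, Hoxb and Hist families, with 2, 1 and 3 genes left, no longer passed (adjusted p = 0.258, 0.809 and 1, Fisher's exact test).

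Occupied promoters were richer in CpG than others, but the richest promoters were not the most often occupied. The mean ratio of observed to expected CpG was 0.56 ± 0.169 (SD over 2480 occupied promoters), as against 0.438 ± 0.257 over the others (permutation test, two-sided, p = 1e-05, the smallest it can give). Single promoters went both ways: the occupied Klf14 and Igf2 promoters had ratios of 0.97 and 0.171, and the unoccupied Ezh2 and Alb promoters had 0.888 and 0.26. Over 10 equal groups of promoters by this ratio, the occupied share was 0.411% (0.188 to 0.778) in group 1, 21.1% (19.4 to 22.9) in group 5 and 9.95% (8.73 to 11.3) in group 10. Replicate 1 had 31.5% in group 5 and 14.0% in group 10, and replicate 2 had 20.3% and 9.63%.

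**Figure D3:**
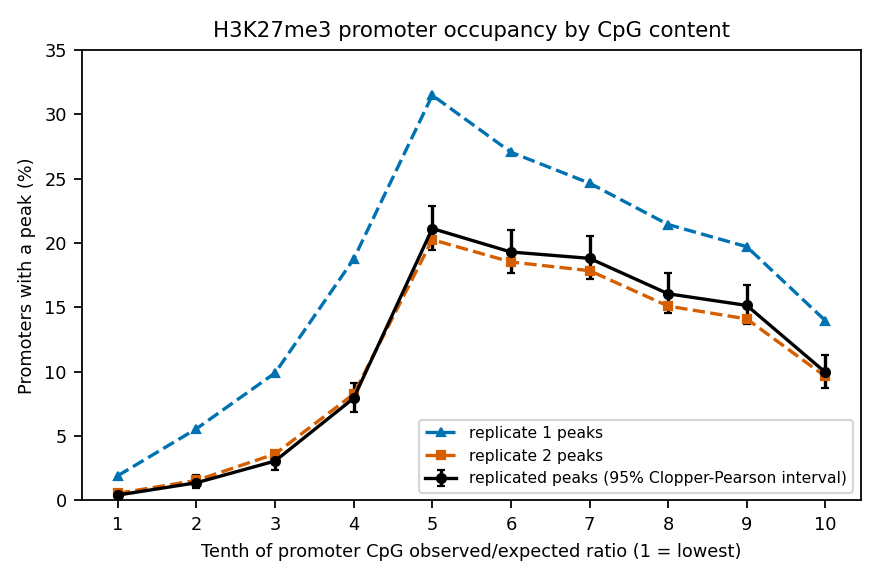
Share of promoters with a peak, in percent, in 10 equal groups of promoters ordered by the ratio of observed to expected CpG (1 lowest). Circles show replicated peaks with exact 95% intervals, triangles replicate 1 and squares replicate 2; the replicated share is highest in group 5 (21.1%) and is 9.95% in group 10.

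Covered base pairs lay in promoters and exons more than shifted peaks did. Promoters held 16.5% of the base pairs of replicated peaks, against 1.75% ± 0.16 (SD of 1000 shifts) for shifted peaks, a ratio of 9.38. Exons held 12.7%, a ratio of 2.64, and intergenic sequence 30.5%, a ratio of 0.607 (permutation by circular shifts, two-sided, p = 0.001 for each of these 3 classes). Introns held 40.3% against 43.2% ± 1.56, a ratio of 0.934 that did not pass the threshold (permutation by circular shifts, p = 0.071). With promoters of 2.5 kb either side, introns had a ratio of 0.741 (permutation by circular shifts, p = 0.001). The ratio for promoters was 6.86 in replicate 1 and 8.95 in replicate 2.

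Among the chromosomes with peaks, X had the least covered length per Mb in all 4 lists. Replicated peaks covered 1.20 kb per Mb of X, against a median of 6.50 and a range of 3.27 to 12.3 over the 19 autosomes. Chromosomes 19 (12.3) and 11 (11.98), the latter with the HoxB cluster, had the most. The value for X was 4.50 kb per Mb in the pooled list, 4.40 in replicate 1 and 1.11 in replicate 2, with autosome medians of 9.60, 9.89 and 4.47. Each chromosome gives 1 value per list, so no test was made. No list had a peak on chromosome Y.

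**Figure D4:**
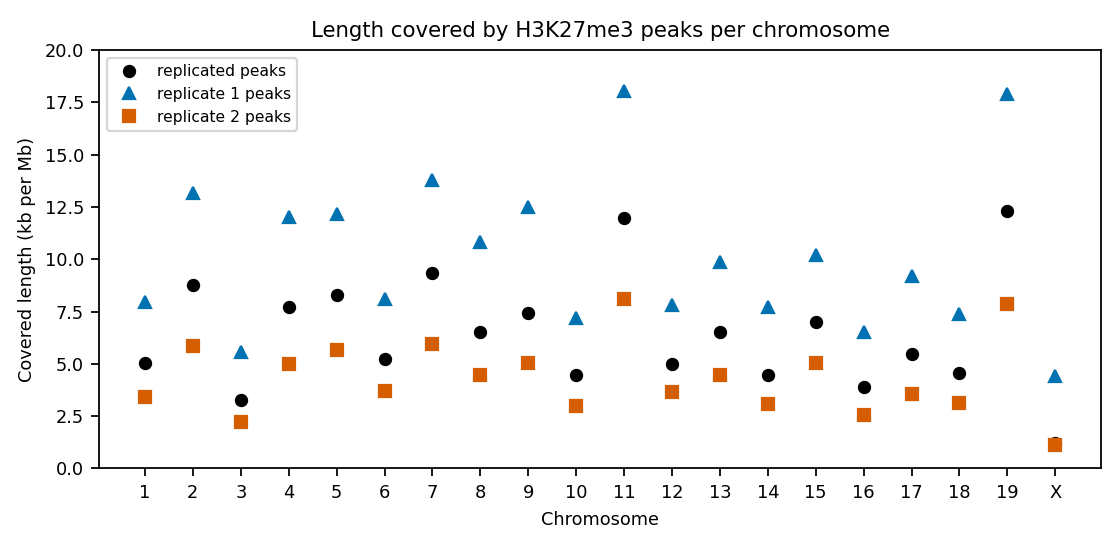
Length covered by peaks per chromosome, in kb per Mb. Circles show replicated peaks, triangles replicate 1 and squares replicate 2; chromosome X lies lowest in each, at 1.20, 4.40 and 1.11.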

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

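The alternatives with peaks of −log10 q of 2 or more, with replicated peaks overlapping both replicates and without chromosome Y were chosen only after the data were seen. Of 362 values of the main results under alternatives, 322 kept their direction and their side of the threshold, or stayed within 1.5 times a count. Of the 19 lists, 13 did so under all 12 alternatives. Leaving out chromosome Y could change little, because no list had a peak there. Its values for the 19 lists and for the count of occupied promoters are among those that stayed. Both replicate overlaps passed at p = 0.001 (permutation) under each of the 5 alternatives tried. For the values that changed, the cause was not tested, except that 1 gene per 100 kb leaves fewer genes to test. Read depth is unknown, so whether the shorter list of replicate 2 reflects fewer reads cannot be told from these files, and a promoter without a peak may hold signal under the threshold of the caller (at −log10 q of 5 or more, 1467 promoters were occupied, against 2480). No paired analysis was possible because there is only 1 group. Differences below are in percentage points, and adjusted p-values are by Fisher's exact test or permutation.

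With one replicate's list alone, occupied promoters ranged from 2398 to 3823 and domains from 9490 to 28542. Differences from other genes ranged from 12.4 to 15.9 for pan-neuronal genes, 16.3 to 23.5 for endothelial and mural cell genes, 17.6 to 39.7 for cell cycle inhibitors and -2.12 to 0.1995 for Polycomb subunits. The mesoderm list exceeded forebrain patterning by 6.08 to 22.1 and forebrain patterning exceeded neuron subtype by 24.5 to 25.9. The excess in spread ranged over 751.5 to 1634 bp for synaptic, 595 to 2521 bp for astrocyte and oligodendrocyte, -84 to 502.5 bp for pluripotency and -116 to 1246 bp for structural genes.

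With the pooled list, pan-neuronal (20.0) and endothelial genes (28.8) passed. With −log10 q of 5 or more, housekeeping no longer passed (-6.71), the mesoderm list exceeded forebrain patterning (34.1), and 3 pairs no longer passed: forebrain patterning against neuron subtype (16.0), pan-neuronal against synaptic (-24.9) and pan-neuronal against housekeeping (13.3). At −log10 q of 2 or more, the mesoderm pair passed (22.1) and the neuron subtype pair did not (21.3). With peaks overlapping both replicates, housekeeping did not pass (-9.85) and the mesoderm pair did (19.6). A 0.5 kb window ended the housekeeping call (-9.35). A 2.5 kb window brought pan-neuronal (16.3), Polycomb (18.7) and cell cycle genes (57.8) past the threshold, and the intron ratio of 0.741. Any transcript start did so for pan-neuronal (20.7) and cell cycle genes (58.8) and the mesoderm pair (16.6), and reversed structural genes (-1.22). CpG matching brought structural genes past it (8.98). With 1 gene per 100 kb, Polycomb (-4.12) and structural genes (-13.2) reversed, housekeeping did not pass (-13.2), and 10 families were higher and 4 lower.

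Over the 12 alternatives, adjusted p ranged from 0.00443 to 0.214 for pan-neuronal, 0.00284 to 0.298 for endothelial, 0.00678 to 1 for Polycomb, 0.00103 to 0.45 for cell cycle, 0.0409 to 1 for structural and 0.0027 to 0.651 for housekeeping genes. For the pairs, over the 9 alternatives tried, it ranged from 0.00148 to 0.452 (mesoderm against forebrain patterning), 0.00847 to 0.22 (forebrain patterning against neuron subtype), 0.00149 to 0.0567 (pan-neuronal against synaptic) and 0.000356 to 0.0567 (pan-neuronal against housekeeping), and for spread, over the 3 alternatives tried, from 0.0183 to 0.493 (astrocyte and oligodendrocyte) and 0.011 to 0.118 (synaptic). Of 107 named genes, 97 kept their state with the list of replicate 1, 102 with that of replicate 2, and 106 at −log10 q of 5 or more (Cdkn2b lost its peak). The 5 genes per replicate named for a peak absent from the replicated list change state with that replicate's list by rule. Many other occupied genes were named for high enrichment. These counts therefore do not measure how well promoter states hold in general.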

Other observations

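The test of weak peaks among those without overlap in replicate 2 and the tests of chromosome X by 20 groups and by overlap with replicate 1 were chosen only after the result was seen, and the 4 peaks of high −log10 q were picked out after their values were seen. Several receptor and ion channel families were among the other symbol families occupied more often than the remaining genes. Values after the counts are adjusted p by Fisher's exact test over 283 families, values after gene names are enrichments, and the members were chosen after their values were seen. Serotonin receptor genes (Htr) were occupied at 9 of 14 promoters (adjusted p = 9.7e-05, Fisher's exact test), with Htr6 (7.28) and Htr7 (6.13) highest. Two-pore potassium channel genes (Kcnk) were occupied at 8 of 14 (0.000927), with Kcnk9 (8.43) highest, inward rectifier genes (Kcnj) at 7 of 15 (0.0105), with Kcnj12 (7.28), and calcium channel genes (Cacna) at 7 of 14 (0.00695), with Cacna1i (5.96). Synaptotagmin genes (Syt) were occupied at 7 of 17 (0.0211), with Syt2 (6.52) highest; Syt1 had no replicated peak. The broad solute carrier (Slc, 70 of 371, 0.000359), G protein-coupled receptor (Gpr, 18 of 73, 0.0171) and phosphodiesterase (Pde, 9 of 26, 0.0209) families were also higher.

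The other families occupied more often included collagens (Col, 17 of 45, adjusted p = 9.7e-05, Fisher's exact test), with Col13a1 (7.44) highest, integrin alpha genes (Itga, 6 of 12, 0.0157) and Adamts proteases (7 of 19, 0.0392). Fibroblast growth factors (Fgf, 10 of 22, 0.00122) had Fgf3 (8.43) and Fgf8 (8.05) highest, and Bmp genes were occupied at 7 of 12 (0.0021). Prdm factors were occupied at 6 of 14 (0.033), with Prdm13 (7.94), a factor of spinal cord and retinal neurons, highest. Translation initiation factor genes (Eif) were occupied at 0 of 55 (up to 6.49%), fewer than other genes (Fisher's exact test, adjusted p = 0.0274). Against promoters of like CpG ratio, Syt, Prdm and Adamts did not pass (adjusted p = 0.121, 0.12 and 0.121 by permutation). With 1 gene per 100 kb, which leaves fewer members, these 3 families did not pass either (0.809, 0.294 and 0.15), nor did Kcnk (0.106), Slc (0.108), Fgf (0.288), Pde (0.499), Itga (0.516) and Eif (0.787), all adjusted p by Fisher's exact test.

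Pooled peaks on chromosome X were in the replicated list less often than autosomal ones (15.2% of 2576, 13.8 to 16.6, and 35.4% of 48171, 34.9 to 35.8). Autosomal peaks of like enrichment and width (10 equal groups of each) gave an expected 19% for X, a ratio of 0.797 (0.726 to 0.873). With 20 groups of each and blocks of 5 Mb resampled, the ratio was 0.732 (0.639 to 0.794). Ties in enrichment or width were ordered by chromosome with X last. A tie across a group boundary therefore tended to place X peaks in the higher group. This can raise the share expected for X, which was 20.7% with 20 groups. Both intervals exclude 1, but for this reason they cannot decide whether weaker and narrower peaks are the whole cause. Whether such peaks explain the pattern as far as the bound of 0.8 set in advance for 10 groups cannot be told. The first interval spans that bound. A second candidate explanation is that X peaks come from the weak tail of the longer list of replicate 1: its share of peaks on X fell from 4.24% in all to 2.55% at the length of replicate 2, which had 2.76%, a ratio of 0.924 (0.835 to 1.02), so the prediction written in advance for that hypothesis was met. As the whole cause this is argued against, since the pooled list had 5.08% of its peaks on X, above both replicates, and 48.6% (46.4 to 50.7) of the 2185 X peaks outside the replicated list overlapped no peak of replicate 1, against 40.3% (39.8 to 40.9) of such autosomal peaks. Whether that tail explains part of the pattern cannot be told, since 35.2% of those X peaks lay in it, against 34.7% of autosomal ones. The mix of male and female embryos in each pool stays open, and no biological explanation was tested.

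Of the 17421 replicated peaks, 4371 had no overlapping peak of replicate 2. They were 1.98% (1.54 to 2.5) of the highest of 5 equal groups by enrichment and 40.5% (38.9 to 42.2) of the lowest, and 73.1% of them (71.8 to 74.4) had a peak of replicate 2 within 3 kb, against 3.46% after shifts (permutation by circular shifts, two-sided, p = 0.001). These values meet the predictions of 2 explanations that may both hold, weak peaks missed in the shorter list and domains broken up differently by narrow calls. The enrichment used for the 5 groups is that of pooled peaks, to which replicate 2 contributes. Peaks absent from replicate 2 would therefore tend to rank low for any cause. The first test cannot separate weak peaks that were missed from sites without the mark in replicate 2. The second test does not exclude chance placement of weak peaks inside broad marked regions. As the design has 1 group, no biological explanation was tested.

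The 3 highest −log10 q values of the replicated list were not at the peaks of highest enrichment. They were 158.8 and 103 at neighbouring peaks on chromosome 17 (39843002 to 39846809 and 39847583 to 39848932), both overlapping Rn18s-rs5, a pseudogene of 18S ribosomal RNA, and 86.4 in Cdk8 on chromosome 5 (146260997 to 146261489), with enrichments of 4.01, 3.001 and 6.36. A 4th such peak, in the noncoding gene Gm36876 on chromosome 11 (109011583 to 109012088), had 34.7 and an enrichment of 2.67. A candidate explanation is reads from repeated sequence, and copies held in the assembly were argued against, since 0 of the 4 peaks had a median of 2 or more exact genome matches over sampled words of 50 bases. Copies missing from or collapsed in the assembly stay open, and no biological explanation was tested.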
